A study of Zea mays with 2 samples.

How the data were processed

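RNA-seq had been made from endosperm of maize kernels at 18 days after pollination, with 1 library from wild-type (WT) kernels and 1 from kernels of the defective kernel mutant dek37. RNA was extracted with Trizol, cleaned on columns and treated with DNase, and libraries followed standard Illumina protocols, per the labels' protocols. Bowtie 0.12.2 is named in the submitters' processing notes. The genome build, the annotation, the counting program, the treatment of reads that map to several places and any filter are not given in the sources used here.

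The deposited values are RPKM, reads per kilobase of length, scaled to the reads of the library, per the file headers. Each file lists the same 56848 entries, identified by a chromosome and a start and end position and by nothing else. The entries fall on 50685 distinct loci, none of which overlaps another. A total of 11672 entries share their locus with at least 1 other entry, up to 8 at 1 locus, and whether these are transcripts or genes is not stated. Values are therefore reported per entry. Starts are printed 1-based. The deposited starts were read as counted from 0, because RPKM multiplied by the end minus the start gave whole reads in both libraries for 615 entries, against 198 when 1 base was added to the length (within 1e-06 of a whole number, relative above 1 read).

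No gene names were assigned. The deposited files hold positions and no gene identifiers, and name no genome build, so that they could not be joined to the gene table at hand, which is for 1 named assembly. The 27 gene lists fixed before the data were examined (storage proteins, starch synthesis, mitochondrial complexes, markers of other kernel cell types and others) need names and were not run, and the level of the dek37 gene itself was not analysed here.

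Depth was read back from the RPKM values. The commonest product of RPKM and locus length gave a total of 19106174 reads for the dek37 library and 18139532 reads for the WT library, both whole numbers to within 1e-07 reads. For 56842 of the 56848 entries (99.99%), a length between 30 and 25000 bases then gave whole reads in both libraries, to within a relative tolerance of 1e-09. The search allowed only 1 read or an even number of reads. Of the 615 entries with whole reads at their full span, 523 (85.0%) had 1 or an even number of reads in both libraries. That is what counting 2 reads per fragment and writing 1 read in place of 0 would give, but no source states it. Neither file holds a zero, and the smallest values (0.0121 RPKM in dek37 and 0.0128 RPKM in WT) are those of 1 read. The read numbers given below are the smallest that fit, and they sum to 89.6% of the dek37 total and 89.9% of the WT total. On 2000 simulated entries, this recovery returned the true ratio for 100% and the true reads for 87.45%, and it never gave more reads than were simulated. The simulated reads followed the same rule of 1 or an even number, so the rule itself was not tested.

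Because RPKM are not counts and there was 1 library per genotype, no count model was fitted and no p-value is given for any difference between the genotypes. Differences are log2(RPKM + 1) in dek37 minus log2(RPKM + 1) in WT. This pseudocount understates changes of low entries. An entry was counted as differing where that difference was at least 1 (2-fold) in size and the higher value was at least 10 RPKM. Ratios of single entries carry exact (Clopper-Pearson) 95% intervals, computed on fragments of 2 reads, with the 1-read value counted as 0. Medians over entries carry 95% binomial (order-statistic) intervals. Intervals of single entries cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals of medians describe the spread over entries taken as independent. Entries that share a locus or reads are not, so these intervals may be too narrow. None of the intervals says anything of the spread between kernels or plants. The median of a set of entries was placed among 10000 random sets of the same size, matched on mean RPKM in 20 bins, over entries with a mean of at least 1 RPKM.

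Fixed before the data were examined were the thresholds, the matched random sets and the rule for single entries: with no names, the 2 with the largest increase and the 2 with the largest decrease. Sets by chromosome, classes of abundance and groups of neighbouring abundant loci (at least 3 loci with a mean of 1000 RPKM or more, no more than 1 Mb apart) were chosen after the data were examined. The alternatives were pseudocounts of 0.1 and 5, floors of 0, 1 and 50 RPKM, a 4-fold threshold, and 3 other scalings: a median difference of 0, a trimmed mean of M values (trims of 30% and 5%), and equal totals without the 50 most abundant entries. The use of 1 entry per locus was added later. On data simulated from the WT profile with counting error alone, 100% of entries raised 4-fold and 97% of those lowered 4-fold were counted, together with 158 of 14260 unchanged entries (1.11%). Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.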

Results

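Transcript levels were compared between endosperm of WT maize kernels and endosperm of kernels of the mutant dek37, both collected 18 days after pollination, when the starchy endosperm fills with storage protein and starch. As background, dek mutants form defective kernels, and DEK37 has been described as a pentatricopeptide repeat protein of mitochondria that takes part in the splicing of a mitochondrial transcript. The comparison asked how the endosperm transcriptome of the mutant differs from that of the wild type. There was 1 library per genotype, with 19106174 reads for dek37 and 18139532 reads for WT, so the differences below describe 2 libraries and have no replicate check. No p-value can be given. Positions are those of the deposited files, whose genome build is not given in the sources used here, and the entries carry no gene names. Whether a position lies in an exon, an intron or a UTR was not analysed here.

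The most abundant transcripts of the WT endosperm were about 3-fold lower in dek37. Among the 20 entries with the highest mean RPKM, 19 were lower in dek37 and 18 were at least 2-fold lower. The median log2 difference of all 20 was -1.67, which is 3.18-fold, with an SD of 0.463 and a range from -1.81 to 0.24; the 18 entries picked as 2-fold lower ran from -1.81 to -1.35. The ranking did not set the direction, since 14 of the 20 most abundant entries of the dek37 library itself were also at least 2-fold lower there than in WT, while 4 were at least 2-fold higher. By that ranking the median was -1.63, with an SD of 1.38 and a highest difference of 2.34. Maize endosperm is known for a few highly expressed families of storage protein genes, but which of these entries belong to such families was not determined.

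The most abundant entry of all, at chromosome 6, 44381573 to 44382522, had 65773 RPKM in WT and 19769 RPKM in dek37. WT exceeded dek37 there by a factor of 3.33 (counting interval 3.30 to 3.35). The 1 exception among the 20 lay at chromosome 1, 178476591 to 178478157, with 17534 RPKM in WT and 20708 RPKM in dek37, which made it the most abundant entry of the mutant library. Its difference of 0.24 was below the general shift described next, and it became -0.16 once that shift was removed. Both entries were chosen after their values were seen. Near-identical gene copies can share reads, and how such reads were counted is not given, so levels of single members of a family are uncertain.

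**Figure D1:**
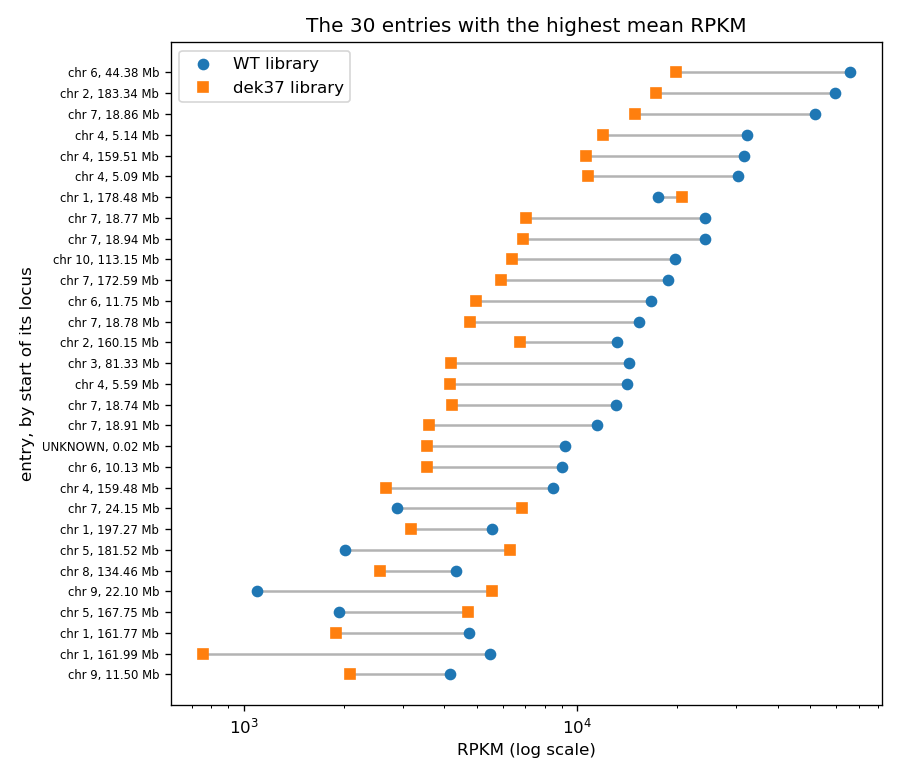
RPKM on a log axis in the WT library (circles) and the dek37 library (squares) for the 30 entries with the highest mean, labelled by the start of their locus; a grey line joins the 2 values of an entry. The dek37 value lies below the WT value for 25 entries and above it for 5.

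The make-up of the 2 libraries differed accordingly. The 20 entries with the highest mean took 35.9% of the summed RPKM in WT and 14.1% in dek37, and the top 50 took 43.0% and 20.4%. Recovered read numbers are the smallest that fit, so shares in reads are approximate: the top 50 held 28.9% of the WT total and 13.5% of the dek37 total, or 32.1% and 15.1% of the recovered reads. Most other entries with at least 10 RPKM were a little higher in dek37. Of 17017 entries with at least 10 RPKM in the higher library, 13156 (77.3%) had a positive difference, and the median was 0.39 (interval 0.38 to 0.40). The size of a change of a single entry depends on whether this shift is taken as the baseline, and which baseline is right was not tested.

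Abundance separated the 2 behaviours. In every class from a mean of 1 RPKM up to 1000 RPKM the median difference lay between 0.29 and 0.42. The 21840 entries with a mean below 1 RPKM, where the pseudocount outweighs the values, had a median of -0.0087, with 13913 lower and 7927 higher. The median was -0.17 (interval -0.59 to 0.05) for the 60 entries with a mean of 1000 to 3000 RPKM. For the 31 entries with a mean of 3000 RPKM or more it was -1.63 (interval -1.73 to -1.32), and 22 of these were at least 2-fold lower. Of all 91 entries with a mean of at least 1000 RPKM, 35 were at least 2-fold lower and 11 at least 2-fold higher. The 11 higher entries lay on 9 chromosomes, with dek37 levels from 1483 to 6831 RPKM and log2 differences from 1.02 to 2.46. After the shift was removed, 6 entries remained at least 2-fold higher and 47 were at least 2-fold lower.

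**Figure D2:**
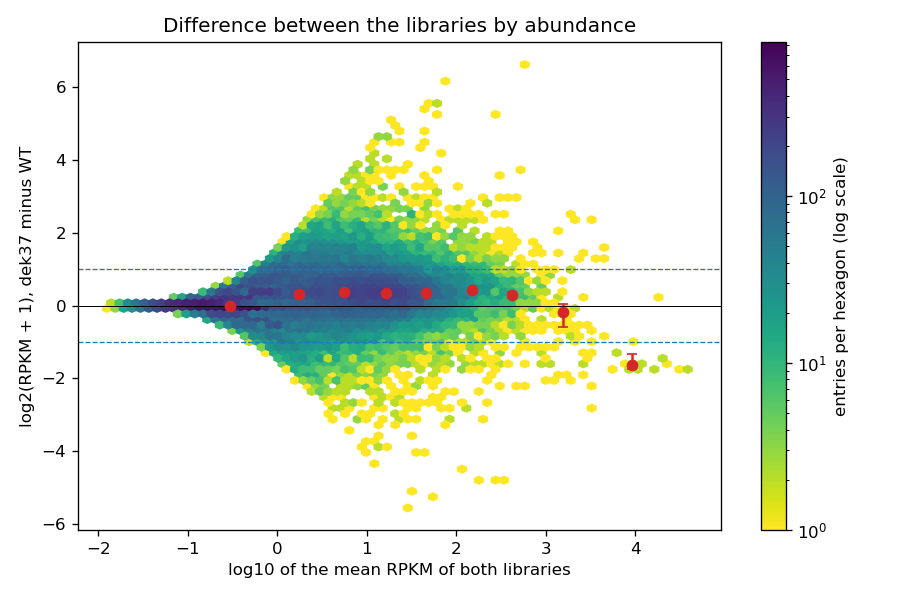
Difference between the libraries (log2(RPKM + 1), dek37 minus WT) against the log10 of the mean RPKM for all 56848 entries, shaded by the number of entries per hexagon on a log scale. Red points are class medians with 95% binomial intervals and dashed lines mark 2-fold; the class of 3000 RPKM or more has a median of -1.63, and the classes from 1 to 1000 RPKM lie between 0.29 and 0.42.

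Several abundant loci were neighbours, in 3 groups. On chromosome 7, 7 loci with 8 entries lay between 18744943 and 18944704, a stretch of 199.8 kb. WT levels there ran from 1504 to 51613 RPKM and dek37 levels from 521 to 14974 RPKM. All 8 entries were lower in dek37, with log2 differences from -1.82 to -1.53 (median -1.73, SD 0.101). Whether these entries share reads was not determined, so their 8 differences may not be independent. This stretch alone took 10.5% of the summed RPKM in WT and 3.51% in dek37. A second group, of 4 loci on chromosome 4 between 5075029 and 5591069, had log2 differences from -1.77 to -1.44. The third group, on chromosome 6 between 39088029 and 39893787, was uneven, since 1 of its 4 entries was at least 2-fold lower (-1.98) and the median was -0.34. Of the other entries with at least 10 RPKM inside these stretches, 13 of 16 on chromosome 4 were higher in dek37 (median 0.28), as were all 5 on chromosome 6 (median 0.92), whereas the 1 on chromosome 7 was lower (-0.63).

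**Figure D3:**
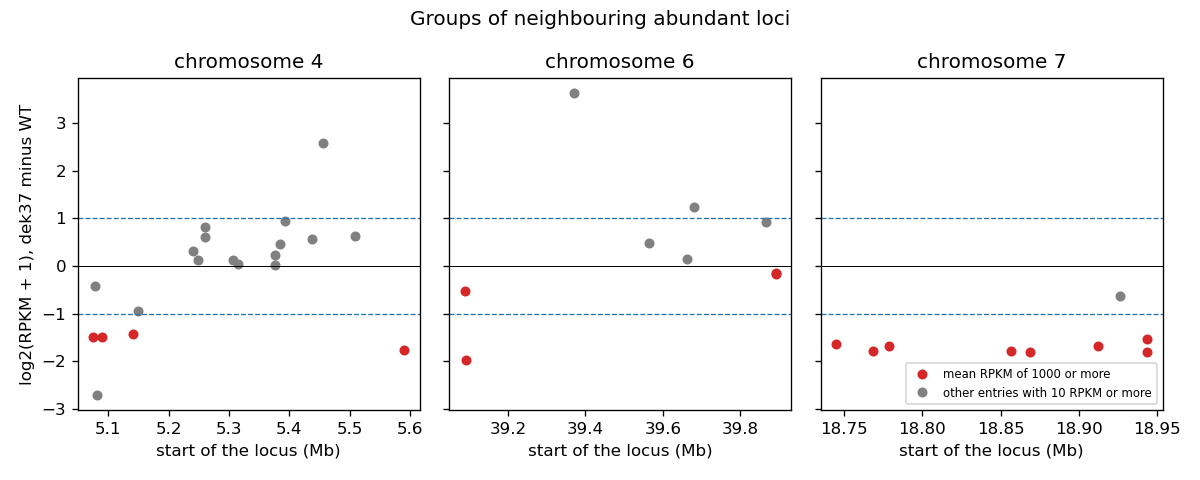
Difference between the libraries (log2(RPKM + 1), dek37 minus WT) along the 3 groups of neighbouring abundant loci, by the start of the locus in Mb. Red points are entries with a mean of 1000 RPKM or more, grey points are other entries with at least 10 RPKM, and dashed lines mark 2-fold; on chromosome 7 all 8 red points lie between -1.82 and -1.53.

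Across the whole table, 2523 entries (14.8% of those with at least 10 RPKM) were at least 2-fold higher in dek37 and 523 (3.07%) at least 2-fold lower. They lay on 2368 and 497 distinct loci. This split depended on the scaling: with the median difference set to 0, 1237 entries were higher and 1006 lower, so that the share of higher entries went from 82.8% to 55.1%. All 523 lower entries were among the 1006, and all 1237 higher entries were among the 2523. This had to be so, because the rescaling divides every dek37 value by the same factor and so lowers every difference. The counting interval excluded equality, at the library totals read back from the values, for 2919 of the 3046 entries (95.8%). These entries had been picked for a difference of at least 2-fold, so most were bound to pass. Intervals relative to the general shift were not computed. Changes of at least 8-fold were found for 95 entries in the upward and 35 in the downward direction.

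On the log2(RPKM + 1) scale, the largest increase was at chromosome 9, 6491044 to 6492220, where a level of 10.8 RPKM in WT (122 reads) stood against 1155 RPKM in dek37 (13798 reads). The ratio was 107 (counting interval 83.5 to 141). Second on this scale came an entry at chromosome 1, 81440902 to 81442942, with 1.08 RPKM in WT (14 reads) and 145 RPKM in dek37 (1982 reads). Its ratio was 134 (counting interval 65.0 to 335). Between these 2 entries the order was reversed with a pseudocount of 0.1 (6.94 for the chromosome 1 entry against 6.73), and other entries were not ranked at that setting. The other entry of that locus had 1.16 RPKM in WT and 85.0 RPKM in dek37. In the opposite direction, the entry at chromosome 1, 287062939 to 287065014, had 60.8 RPKM in WT (1490 reads) and 0.310 RPKM in dek37 (8 reads), so that WT exceeded dek37 by a factor of 196 (counting interval 76.3 to 722). An entry at chromosome 3, 23896367 to 23898018, had 105 RPKM in WT and 1.83 RPKM in dek37, a factor of 57.5 (counting interval 33.4 to 109).

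Some entries were read in effect from 1 library. At the value of 1 read in WT, with at least 20 reads in dek37, stood 154 entries on 152 loci, and the reverse held for 36 entries on 35 loci. Their levels were low, with medians of 2.55 RPKM in dek37 for the first set and 2.40 RPKM in WT for the second. A value of 1 read cannot be told from 0 in these files. Because the read numbers are the smallest that fit, some of these values could also stand for more than 1 read at a greater length.

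Since DEK37 has been described as a mitochondrial protein, entries of the organelle genomes were compared with nuclear ones of similar level. The 39 mitochondrial entries with a mean of at least 1 RPKM had a median difference of -0.06 (interval -0.25 to 0.19), with 17 higher and 22 lower in dek37. The median of all 35008 entries at that level was 0.35, and the mitochondrial median stood at the 0.03 percentile of 10000 random sets matched on level, whose middle 95% ran from 0.07 to 0.59. The random sets were matched on RPKM alone, not on read number or length, and entries were drawn as independent. Relative to the general shift, the median of these 39 entries was lower in dek37. Noise is not excluded, since the 22 with 50 or more reads had a median of 0.02 with an interval from -0.43 to 0.40, which holds 0.35. In RPKM as deposited the mitochondrial entries differed little in sum: all 97 came to 161.7 RPKM in dek37 and 162.0 RPKM in WT. A sum does not show how single entries differed. Over the 37 mitochondrial entries with 20 or more reads, the ratio varied by a chi-square of 2.705 per degree of freedom. No mitochondrial entry was at least 2-fold different above 10 RPKM, a level that 2 of the 97 reached. The 26 chloroplast entries had a median of 0.18 (interval -0.15 to 0.36) and stood at the 9.81 percentile. The 10 nuclear chromosomes had medians from 0.33 to 0.37, all within the middle 95% of their matched random sets, among 13 sets compared. Mitochondrial levels were low throughout, with a highest value of 18.7 RPKM in dek37, and the percentile describes these 2 libraries only.

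**Figure D4:**
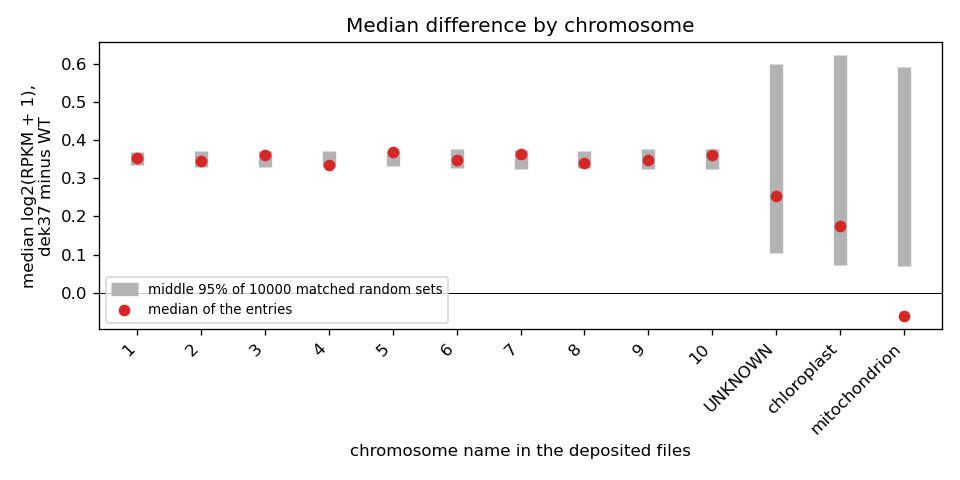
Median difference (log2(RPKM + 1), dek37 minus WT) of entries with a mean of at least 1 RPKM for each chromosome name in the files (red points), with the middle 95% of 10000 random sets matched on level (grey bars). The mitochondrial median of -0.06 lies below its bar, which begins at 0.07.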

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

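With 1 library per genotype no library could be left out, and every difference here may be one between 2 samples as much as between 2 genotypes. No paired analysis was possible because each genotype has 1 library. The planned gene lists were not run because the entries carry no names. Against 2523 higher entries, the count was 1576 with a pseudocount of 5, 1237 with the median difference set to 0, 1236 with the trimmed mean of M values, 1451 with equal totals without the 50 most abundant entries, 5548 with a floor of 1 and with no floor, 639 with a floor of 50 and 441 at 4-fold. Against 523 lower entries, the corresponding scalings gave 1006, 1008 and 852, floors of 1 and 0 gave 1448, a floor of 50 gave 202, and 4-fold gave 124. A pseudocount of 0.1 and 1 entry per locus kept both counts within 1.5 times. The median difference of entries with at least 10 RPKM, 0.39 as deposited, was 0.40 and 0.33 with pseudocounts of 0.1 and 5, 0.092 with equal totals without the top 50, and -0.0013 with the trimmed mean, which sets it near 0 by construction. The abundant entries (mean of 3000 RPKM or more) went further down, from -1.63 to -2.03, -2.03 and -1.93 under the scalings by median, trimmed mean and equal totals. The mitochondrial median went from -0.06 to -0.35, -0.35 and -0.30 under the same scalings. Its percentile stayed at or below 0.08 under these and both pseudocounts. A scaling moves the random sets along with the mitochondrial entries, so the percentile could hardly change and is no check. The 2 members with a mean of at least 10 RPKM had a median of 0.20, at the 33.1 percentile. The entry at chromosome 1, 178476591 changed sign under those scalings, to -0.16, -0.17 and -0.068. In reads in place of RPKM, the share of the top 50 was 13.5% in dek37 and 28.9% in WT, with the smallest reads that fit set against the full totals. The 4 entries with the largest changes kept their direction under every pseudocount and scaling tried, but this is no check. A pseudocount cannot change the sign of a difference, and the largest scaling shift, 0.406 in log2, was far smaller than these changes. Depth limits the low end: 1 read is worth 0.0523 RPKM in dek37 and 0.0551 RPKM in WT for a length of 1 kb. The classes by abundance and the mitochondrial set, with their alternatives, and the use of 1 entry per locus were chosen after seeing the data.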

Other observations

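The tests on scaling, on organelle yield and on the chromosome 8 interval were chosen after the result they bear on had been seen, and those on length, on read number and on a common source were written before their values were computed.

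A short interval on chromosome 8, from 132880859 to 133034976 (154.1 kb), held 4 of the 35 loci that stood at the value of 1 read in dek37 with at least 20 reads in WT. Inside lay 12 entries on 8 loci. The 4 loci held 5 entries with at least 20 reads in WT, at 1.30 to 4.64 RPKM in WT (24 to 52 reads) and 0.0309 to 0.184 RPKM (1 read) in dek37. These reads are the smallest that fit, so the true numbers may be larger in both libraries. Another 3 entries were at 1 read in dek37 with 1 to 18 reads in WT, and 4 had 4 to 18 reads in dek37. In the flanking 300 kb on either side, 7 entries with at least 10 RPKM had a median difference of 0.31 and 1 was at least 2-fold lower. That floor lies above the WT levels of the 5 entries inside. A loss of flanking entries at such levels would not have been seen, so the flanks do not show where the pattern ends. In the reverse direction, the shortest interval with 4 of 152 loci measured 1531 kb. Chance placement was examined by drawing 35 loci from 18687 with at least 20 WT reads and a WT level within the range of the 35. Of 10000 draws, 0 put 4 into an interval as short. Levels were not matched within that range, and loci were drawn as independent of their neighbours. The number 4 and the length were read from the same data, so the draws do not exclude chance. Whether a single uninterrupted segment is missing from the mutant genome stays open. Inside the interval, 3 other loci, picked for having reads in dek37, held 44 dek37 reads and 38 WT reads, so they were not lower in dek37. Reads from similar copies elsewhere could be among them. No entry there had more than 18 dek37 reads, but with so few WT reads an intact segment could hardly have given more. A difference in the genetic background of the kernels near these loci, or silencing of a group of related neighbours, may be followed up with the reads; neither was tested, and the interval was picked because it was the densest.

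The most abundant entries were lower in dek37 while most others with at least 10 RPKM were slightly higher. A scaling factor would move all entries alike, whereas the median log2 ratio of entries with a mean of 3000 RPKM or more minus that of the other tested entries was -2.03 (interval -2.14 to -1.73 with the other median held fixed), so scaling alone is argued against. The gap restates 2 medians already seen as a value that no single factor can change. It shows unequal change and not which of the 2 sets changed in absolute amount, since RPKM are shares of a library. With equal totals of all but the 50 most abundant entries, the median of tested entries was 0.092 in place of 0.39; that scaling assumes that those totals were equal, which was not tested. A bias that lowers all loci with spans like those of the abundant entries is argued against as well. The 4902 entries of 10 to 300 RPKM with spans of 570 to 3090 bp, which held most abundant entries, had a median of 0.4417 (interval 0.42 to 0.46). Spans are those of the locus, so a bias by transcript length was not tested, nor was one confined to the shortest spans. Genotype, a difference in developmental progress or a difference in the tissue collected stay open and untested, since the genotype and the single library cannot be told apart.

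The mitochondrial entries did not share the general rise. A lower yield of organelle RNA in the dek37 library stays open: the chloroplast median of 0.176 had an interval from -0.15 to 0.36, which holds both the mitochondrial median and that of all entries. Noise of thinly read entries is not excluded either, as the 22 mitochondrial entries with 50 or more reads had a median of 0.0189 with an interval from -0.43 to 0.40. A common source such as carried-over DNA would give an even ratio over entries, and the ratio varied by a chi-square of 2.705 per degree of freedom over 37 entries, above 1.89, the upper 0.001 point of its distribution. The rule written before would count this against such a source, but that bound assumed independent fragments, and duplicates of single molecules could raise the value above 1.89, so the source is left open. An effect of the genotype on mitochondrial transcripts is a hypothesis that these libraries cannot separate from the technical ones.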
